A study of Mus musculus with 3 samples.

How the data were processed

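Anti-FLAG ChIP-seq was done on tongues of E12.5 mouse embryos homozygous for a 3xFLAG-tagged endogenous Foxf2. Per the labels, 2 ChIP libraries and 1 input library were made with the ThruPLEX kit and sequenced on an Illumina NextSeq500. The labels give 75 dissected tongues on each sample, and whether this is per library or in all is not stated. Per the submitters' processing notes and design text, reads were aligned to mm10 with Bowtie2 (version 2.4.1) and handled with SAMtools (version 1.7.1), and peaks were called with HOMER (version not given in the sources used here) with the input as control. The peak caller's parameters, the read depth, and whether the ChIP libraries were pooled before calling are not given in the sources used here.

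The values used were 1 table of 25707 peaks. The score of each peak is the authors' value as deposited, from the column headed peak score. Its scale is not stated, and it was used to rank, describe or filter peaks. The 1 exception is the closing test of a single active X copy, which takes the score as proportional to reads. The last column, per the file headers either a focus ratio or a region size, was read as the focus ratio, since every peak has the same width and the values are fractions between 0.499 and 0.999. It is as deposited by the authors from the same caller, and a higher ratio is taken as a sharper peak. Peak numbers ran within each chromosome to a total of 27406, so 1699 numbers (6.20%) had no peak in the table, and the step that removed them is not stated. No column belonged to a single library. Replicate comparisons and values of ChIP over input, both planned before the data were examined, could therefore not be run here.

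Coordinates were used as deposited, in mm10, with the sequence of the same build (GRCm38) and GENCODE M21 basic transcripts. The 3 peaks on an unplaced contig were left out, leaving 25704. The planned use of the caller's own promoter class gave way to classes computed here, since the table holds none. The class at the peak centre was taken in the order promoter (1000 bp upstream to 100 bp downstream of a TSS), transcript end (100 bp upstream to 1000 bp downstream), coding exon, 5' and 3' untranslated region, noncoding exon, intron and intergenic. The nearest gene was that of the nearest protein-coding TSS. Random shares came from 1000 placements of the peaks on their own chromosomes outside assembly gaps.

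Motifs were matched on both strands in the 200 bp around the peak centre and in windows of equal width 2000 bp upstream and downstream. Exact McNemar tests were run against each side, the larger p was kept and Benjamini-Hochberg adjustment was made over 31 motifs. A two-sided permutation test with 100000 resamples was used for the relation with score, and two-sided Fisher's exact tests for promoter peaks. Each of 21 gene lists was compared by the share of its genes with at least 1 peak, with 10000 random lists of protein-coding genes matched on territory length in 10 bins, list members left out of the draw. The p was two-sided and adjusted over the 21 lists, with a threshold of 0.05. Intervals of shares are exact (Clopper-Pearson) at 95% and cover counting of peaks only.

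Motifs, gene lists and the rule for named genes were fixed before the data were examined. The rule takes the genes nearest to the 10 highest-scored peaks, and the 10 genes with the most peaks. It adds Foxf2, Foxf1 and every gene with a peak in the Hedgehog, HGF and MET, and TGF-beta lists, and up to 4 genes with the most peaks in each other list. Members of a list said to have no peak, and single peaks described in detail, were chosen after their values were seen. Alternatives covered the peak list, window, motif form, background, promoter width, distance to TSS, matching and clustering of peaks.

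The tests were tried on simulated data. The McNemar test was run between the flanks of 200 random sets of 2571 peaks with the sides swapped at random. It called 3% of the sets at p of up to 0.05, and 96.5% after a match was added to 5% of the windows of 1 side. With the peaks placed at random, 4% of 200 random lists of 25 genes were called at p of up to 0.05, and 88.5% of lists were called after a peak was added to 50% of their members, both with 1000 random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.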

Results

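Chromatin bound by the forkhead transcription factor Foxf2 was profiled in the developing mouse tongue. The mice carried a 3xFLAG epitope tag on the endogenous Foxf2 protein, placed there by CRISPR genome editing, and tongues were dissected from homozygous embryos at E12.5. Chromatin was precipitated with an antibody against FLAG and sequenced (ChIP-seq), and unprecipitated input chromatin served as the control. The series held 2 FLAG ChIP libraries and 1 input library, and the labels give 75 tongues for each of the 3 samples without saying whether this is the number per library or in all. The values analysed here were a single list of 25707 peaks, each with a position in the mm10 build, a score and a focus ratio from the authors' peak caller. The list gave no values per library, so no difference between the ChIP libraries and the input, and no agreement between the ChIP libraries, was tested, and the sequencing depth was unknown. Every comparison below was made across peaks or across genes of this 1 list. Peaks and genes are not biological replicates, and the p-values describe this list only.

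Foxf2-FLAG peaks were 212 bp wide (end minus start) and scored from 10.1 to 243.9, with a median of 16.2. They were spread over all autosomes at a mean of 10.6 peaks per Mb of sequenced bases, from 8.92 on chromosome 7 to 12 on chromosome 18. The X chromosome held 367 peaks, or 2.24 per Mb, and the Y chromosome held 7. Neighbouring peaks were a median of 39516 bp apart, and 21% of neighbouring pairs lay within 10 kb of each other.

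The placement of the peaks relative to genes was compared with random positions, since the study set out to find the target genes of Foxf2. Peaks lay mostly in introns (45.4%, exact 95% interval 44.8 to 46.0) and between genes (40.7%, interval 40.1 to 41.3). Promoters, taken as 1000 bp upstream to 100 bp downstream of a transcription start site (TSS), held 8.52% of the peaks (interval 8.19 to 8.87). Random placements on the same chromosomes gave 2.58%, so that promoters were 3.30-fold over-represented, and 5' untranslated regions were 5.13-fold over-represented with 0.506% of the peaks. Promoters held 7.66% of the highest-scored decile of peaks and 11.6% of the lowest. The series held no FLAG ChIP from untagged tissue, so binding of Foxf2 at promoters was not separated from recovery of open chromatin. Coding exons held 0.514% of the peaks, 0.395 times the random share. Introns (1.11-fold) and noncoding exons (1.24-fold, p = 0.004, n = 25704 peaks here and for the other classes) were above the random share and intergenic sequence (0.802 times) was below it. Transcript ends (p = 0.855) and 3' untranslated regions (p = 0.0939, n = 25704) were not separated from random placement. The other classes reached p = 0.002 (n = 25704), the smallest value that 1000 placements can give in a two-sided test. The median peak was 51275.5 bp from the nearest protein-coding TSS, and 20.9% of the peaks lay within 10 kb of one, against 16.3% of random positions.

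**Figure D1:**
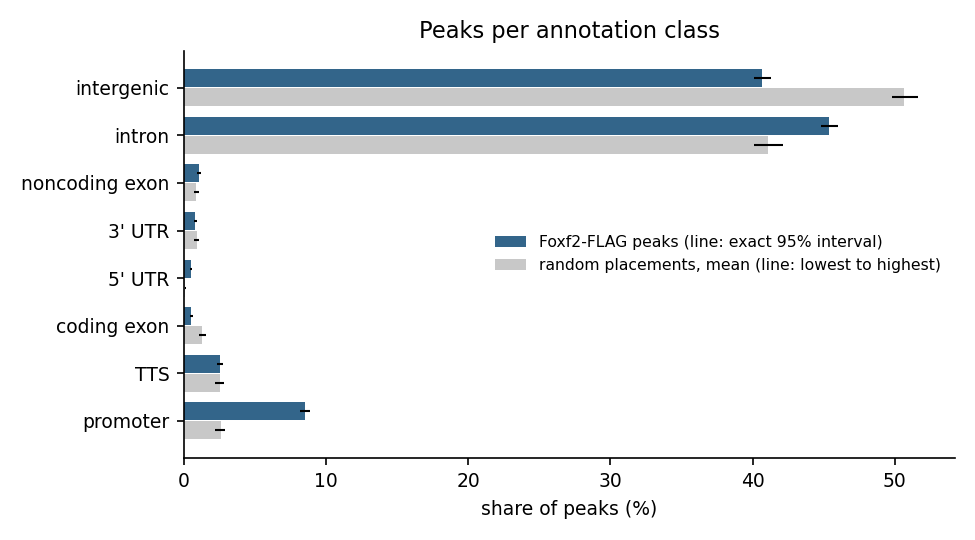
Share of the 25704 peaks on chromosomes 1 to 19, X and Y in each annotation class (x axis, percent), beside the mean of 1000 random placements. Lines are exact 95% intervals for the peaks and the lowest to highest share for the random placements; promoters hold 8.52% of the peaks and 2.58% of the random positions.

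Forkhead recognition sequences were then counted, to ask whether the tagged protein was recovered at sites of the kind that forkhead factors bind. The forkhead core RTAAAYA (R is A or G, Y is C or T) was found in the central 200 bp of 18641 of 25704 peaks, 72.5% (exact 95% interval 72.0 to 73.1). Windows of equal width 2000 bp to either side held it in 18.3%, a 3.95-fold difference whose exact McNemar p was too small for double-precision arithmetic on both sides. The narrower sequence GTAAACA was present in 27.4% of peaks and 3.03% of flanks, a 9.04-fold difference. Of the peaks, 13177 held 1 match, 4308 held 2 and 1156 held 3 or more. Matches were concentrated at the peak centre: 57.5% of those within 100 bp of the centre lay within 20 bp of it. The most enriched 8-base sequence was TGTAAACA, in 15.4% of peaks and 1.17% of flanks. In the 7063 peaks without RTAAAYA the leading sequences were TCTAAACA (7.39% against 1.16%) and TGTTTAAA (8.08% against 1.77%), relatives of the same core, followed by others that include the E-box sequence ACATCTGG (5.75% against 0.942%).

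**Figure D2:**
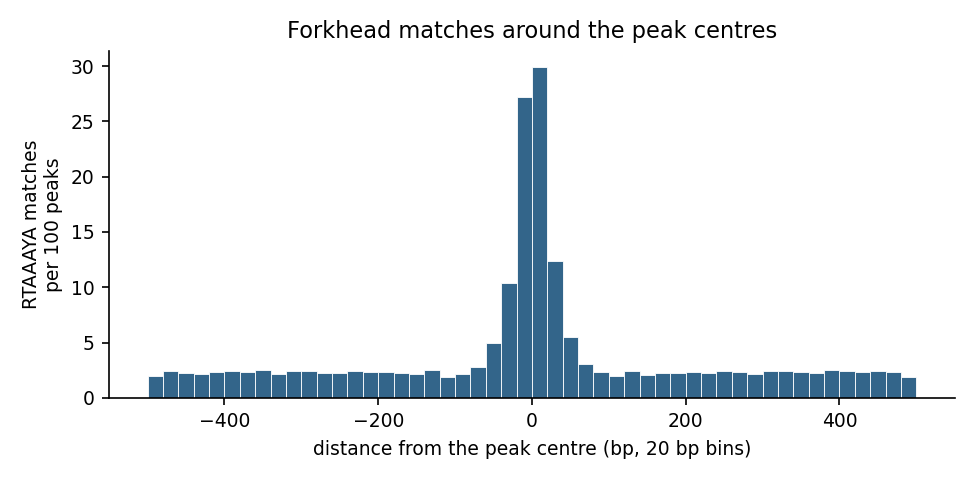
Forkhead matches (RTAAAYA, both strands) per 100 peaks (y axis) in 20 bp bins around the peak centre (x axis, bp). The bins on either side of the centre hold 27.2 and 29.9 matches per 100 peaks, against 1.99 in the bin from -500 to -480 bp.

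Peaks with higher scores carried the forkhead core more often. It was present in 85.6% of the highest-scored decile (exact 95% interval 84.2 to 86.9) and in 63.5% of the lowest (interval 61.6 to 65.4). Across the 25704 peaks Spearman's rho between score and presence of a match was 0.152 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). The score is the peak caller's own value, and this comparison used it only to rank peaks within the list.

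**Figure D3:**
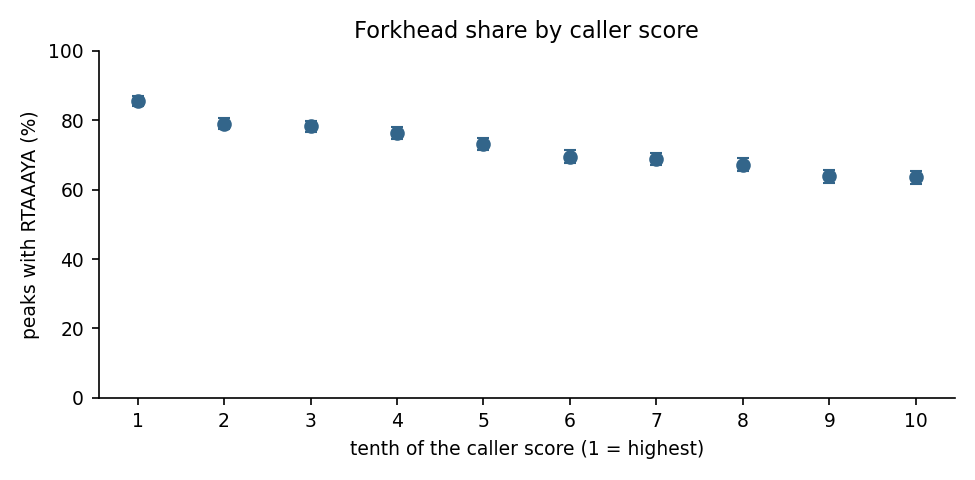
Share of peaks with a forkhead match (y axis, percent) in deciles of the caller score (x axis, 1 is the highest), with exact 95% intervals. The share is 85.6% in the highest decile and 63.5% in the lowest.

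Promoter peaks differed from the remaining peaks in their sequence. The core RTAAAYA was present in 60.1% of the 2191 promoter peaks (exact 95% interval 58.0 to 62.2) and 73.7% of the other 23513 (interval 73.1 to 74.2), an odds ratio of 0.538 (two-sided Fisher's exact p = 1.68e-39). GTAAACA, in contrast, was as frequent in both, with 28% against 27.4% (odds ratio 1.03, Fisher's exact p = 0.548), so the lower share of promoter peaks held for the wider core and was not seen for the strict one. Promoter peaks had a median GC content of 53%, against 43% elsewhere. Within deciles of GC content, an analysis added after the data were seen, the odds ratio for RTAAAYA was 0.757 (95% interval 0.685 to 0.836).

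Sequences of other transcription factor families were tested in the same windows, 28 in all, with Benjamini-Hochberg adjustment over the 31 motifs that include the 3 forkhead forms. Of the 28, 15 were more frequent in peaks than in flanks, 5 were less frequent and 8 did not pass the threshold. E-boxes, the binding sequence of basic helix-loop-helix factors, were among the most widespread: CATCTG was in 28% of peaks and 14.9% of flanks (1.88-fold, adjusted exact McNemar p = 2.34e-282) and CAGCTG in 18.7% and 8.41% (2.22-fold, adjusted p = 4.54e-255). The spaced double E-box bound by Twist factors was rare, in 33 peaks (0.128%) against 4 upstream and 1 downstream flanks (adjusted exact p = 1.98e-06). The TEAD sequence was in 17.8% of peaks against 11.6% (1.54-fold), the short SMAD sequence in 25.1% against 18.3% (1.37-fold) and the sequence TGACAG of TALE homeodomain factors in 17.9% against 13.4% (1.34-fold). Longer forms of these last 2 were not separated from the flanks: the SMAD palindrome GTCTAGAC was in 0.202% against 0.189% and the MEIS and PBX sequence TGATTGAY in 1.13% against 1.29%. The GLI sequence, bound by the transcription factors of the Hedgehog pathway, was in 0.319% of peaks and 0.156% of flanks (2.05-fold, adjusted exact p = 0.000293). Its shorter form GGGTGGTC was in 0.564% against 0.385% (1.46-fold, adjusted exact McNemar p = 0.0185). The CTCF core was 10.2-fold enriched at 1.43% of peaks. The sequences of nuclear receptors (4.17% against 7.18%), T-box factors (0.482% against 0.918%) and SRF (0.833% against 1.17%) were less frequent in peaks, and those of AP-1, RUNX and TAATTA homeodomain factors were not separated from the flanks. Repeat-masked bases were a mean of 13.1% of the peak windows, while 66.5% of autosomal bases lay outside repeats. The flanks were not matched for repeat content, GC content or open chromatin. Neither the higher nor the lower shares of these 28 sequences in peaks were therefore separated from these properties.

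The 10 peaks with the highest scores included 1 near Foxf2 itself. The peak with the highest score in the list, 243.9, lay on chromosome 16 from 30096557 to 30096769, 31.3 kb downstream of the TSS of Hes1, a transcriptional repressor of the Notch pathway. The next, with a score of 231.2, lay on chromosome 13 from 31632485 to 31632697, in intergenic sequence 6.775 kb downstream of the Foxf2 TSS. It held 2 forkhead matches, and the one nearer to the centre read TCTGTATAAACAAGTTA with its 5-base flanks (core at 31632606 to 31632612, minus strand). The third lay in the promoter of Fam53c (score 209.7, chromosome 18, 34759091 to 34759303). The following 7 were nearest to Dock9 (208.1, intron), Eya2 (203.4, intron), Gpbp1 (201.4, intergenic), Sptssa (191.9, intergenic), Dnaic1 (188.8, intron), Setbp1 (186.9, intron) and Usp29 (185.8, intron). Each of these 10 peaks held at least 1 forkhead match. Foxf1, the closest relative of Foxf2, was nearest to 11 peaks, the highest with a score of 81.5, 103.26 kb upstream.

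Of 21938 protein-coding genes, 8172 (37.3%) were the nearest gene of at least 1 peak and 496 were nearest to 10 or more. Zfp608 had 65, followed by Flrt2 and Adgrl2 with 46 each, Auts2 and Robo1 with 44 each, Foxp1 with 42, Runx1t1 with 38, Wwox with 35, and Bnc2 and Cdh11 with 33 each. Flrt2, Robo1 and Cdh11 encode cell adhesion or guidance proteins. A gene with a larger territory, the bases nearer to its TSS than to any other, had more room for peaks: 8.16% of genes in the lowest decile of territory length had a peak, against 81.5% in the highest. Gene lists were therefore set against 10000 random lists matched on deciles of territory length. Peak counts of single genes, here and below, were not matched in this way.

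Of 21 gene lists fixed before the data were examined, 7 had peaks at more of their genes than matched random lists, at an adjusted p of up to 0.05, and none had peaks at fewer. The lists were chosen by knowledge of the tissue, and the Hedgehog, HGF and MET, and TGF-beta lists also by prior knowledge of what this study examined. Genes of cell adhesion and migration had peaks at all 29 members, against a mean of 74.5% in random lists (adjusted p = 0.0042, two-sided, n = 29 genes). Robo1 had 44 peaks, Cdh11 33, Epha4 29 and Efna5 26. Per 100 kb of their territories these were 2.15, 1.41, 2.19 and 1.16 peaks. Put in the same unit, each lay above the autosomal mean (10.6 per Mb), Efna5 and Cdh11 by the least. Transcription factors of the craniofacial mesenchyme had peaks at 36 of 40 members (90% against 65.8%, adjusted p = 0.0042, n = 40), including Zeb2 with 28, Nr2f2 with 27, Meis1 with 26 and Osr1 with 18. Genes of tendon and connective tissue had peaks at 22 of 26 members (84.6% against 60%, adjusted p = 0.018, n = 26). The matrix genes Tnc, Dcn and Col5a1 had 22, 14 and 12. Tcf4, with 28, encodes an E-protein and stood in this list in error for Tcf7l2, a connective tissue marker also called TCF4. Without it, a setting added after the data were seen, 21 of 25 genes had a peak (84% against 59.1%, adjusted p = 0.018, n = 25).

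TGF-beta signalling genes had a peak at 17 of 19 members, against 56.3% in matched random lists (adjusted p = 0.00525, n = 19). The receptors Tgfbr3, Tgfbr2 and Tgfbr1 had 15, 12 and 3 peaks, and the ligands Tgfb2 and Tgfb3 had 11 and 9, whereas Tgfb1 had none. The latent-ligand binding protein Ltbp1 had 15, Ltbp2 4 and Ltbp4 1. The inhibitory Smad7 had 9, Tgfbi and Tgif1 6 each, Smad3 4, Ski 2, and Smad2, Smad4, Eng and Skil 1 each. The highest-scored lay in introns of Tgfbr3 (92.6, chromosome 5, 107268993 to 107269205, and 78.8), followed by one 84.1 kb upstream of Tgfbr2 (69.7). Tgfb3 had a peak 0.451 kb downstream of its TSS (24.2, chromosome 12, 86078484 to 86078696) and Tgfb2 a promoter peak 497 bp upstream of its TSS (13.6, chromosome 1, 186706380 to 186706592).

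Other signalling pathways had peaks at more genes than random lists. BMP genes had them at 19 of 21 members (90.5% against 60.5% in random lists, adjusted p = 0.00525, n = 21), with Bmp2 at 17 and Bmpr1b at 13. WNT genes had them at 29 of 35 (82.9% against 59.3%, adjusted p = 0.00672, n = 35), with Tcf7l2 at 23, Fzd1 and Wnt5a at 16 and Ror2 at 15. FGF genes had them at 19 of 21 (90.5% against 63.3%, adjusted p = 0.018, n = 21), with Fgfr2 at 20, Etv1 at 14, Fgf9 at 11 and Fgf10 at 10. Fgfr2 is annotated from 130162451 to 133123350 on chromosome 7, minus strand. Its count can therefore include peaks near a remote TSS. The WNT call ended with the higher-scored part of the peak list (62.9% against 43.8%, adjusted p = 0.0562, n = 35) and with peaks within 10 kb of a TSS (40% against 23.4%, adjusted p = 0.0957, n = 35). The FGF call ended with peaks within 50 kb (76.2% against 50.6%, adjusted p = 0.0777, n = 21) and with the mean number of peaks per gene (4.90 against 2.86, adjusted p = 0.076, n = 21).

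Hedgehog pathway genes had peaks at 12 of 18 members, 66.7% against 55.0% in random lists, which did not pass the threshold (adjusted p = 0.484, n = 18). The receptor Ptch1, a transcriptional target of the pathway, had 16, of which 13 held a forkhead match. Its highest-scored peak ranked 36 in the whole list (147.4, chromosome 13, 63641758 to 63641970, intergenic, 76.1 kb upstream), and a second lay in its intron 5.82 kb downstream of the TSS (87.6, 63558611 to 63558823). The co-receptors Boc, Gas1 and Cdon had 13, 13 and 7, and the transcription factors Gli3 and Gli2 had 14 and 9, whereas Gli1 and the ligand genes Shh, Ihh and Dhh had none. Disp1 had 6, Hhat and Hhip 4 each, Sufu 3, Scube2 2 and Smo 1. Counting only peaks within 10 kb of a TSS, 50% of the list had a peak, against 22.2% in random lists (adjusted p = 0.0478), and without matching on territory Fisher's exact test gave an adjusted p of 0.0283, so the call depended on the setting.

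HGF and MET signalling genes had peaks at 3 of 11 members, against 36.9% in random lists (adjusted p = 0.863, n = 11). Hgf, the ligand, had 5, including a promoter peak 84 bp upstream of its TSS with 1 forkhead match (score 15.9, chromosome 5, 16553360 to 16553572). Its highest-scored pair, at 33.6 each, lay 248 and 276 kb upstream in introns of the neighbouring gene Cacna2d1. The receptor gene Met had 2 intronic peaks, the higher at 38.5, and the adaptor gene Gab1 had 3.

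**Figure D4:**
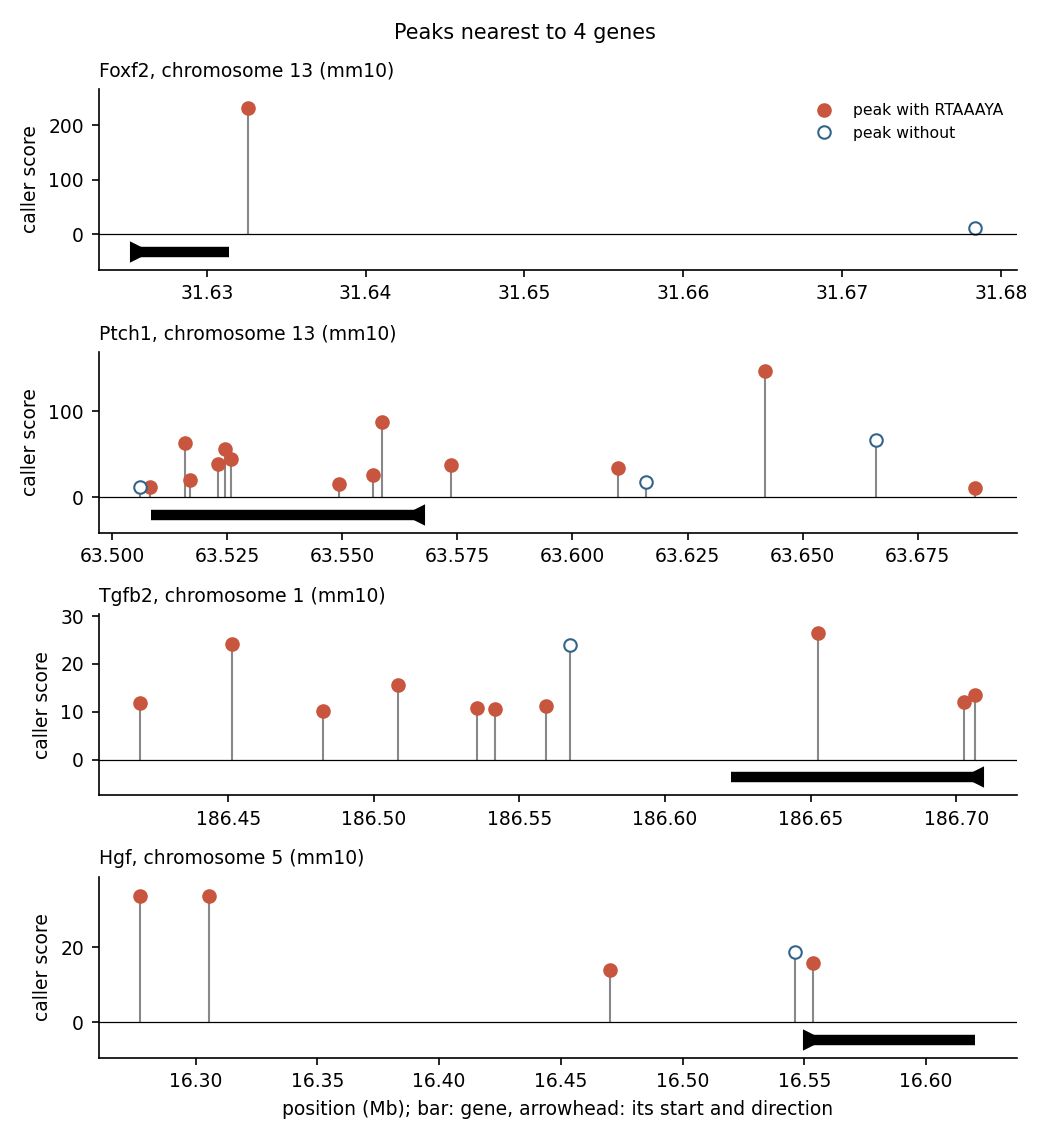
Every peak whose nearest protein-coding TSS belongs to Foxf2, Ptch1, Tgfb2 or Hgf, drawn at its mm10 position (x axis, Mb) and caller score (y axis). Filled points hold a forkhead match, open points hold none, and the bar is the gene; Ptch1 has 16 peaks, 13 of them with a match, and Foxf2 has 2.

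The remaining lists, for other cell types, the liver, general cell functions and the forkhead family, did not pass the threshold. Pericyte and smooth muscle genes came nearest, with peaks at 10 of 16 (62.5% against 35.3%, adjusted p = 0.0703, n = 16), among them Ednra with 11, Pdgfrb with 4, Myh11 with 3 and Abcc9 with 2. Myogenic genes had peaks at 17 of 31 (adjusted p = 0.301, n = 31), led by Pax3 with 11 and Mef2c with 10, and none at Myf5 or Myog. Per 100 kb of territory Pax3 had 2.77 peaks and Mef2c 0.797 peaks. Cartilage and bone genes had them at 12 of 18 (0.442), with 29 at Sox9 and 18 at Runx2. Without matching on territory, the share of these genes with peaks passed by Fisher's exact test (adjusted p = 0.0283, n = 18). Epithelial genes had them at 12 of 25 (0.419), endothelial genes at 8 of 20 (0.899), neural crest and glial genes at 7 of 10 (0.276), neuronal genes at 8 of 15 (1.0), cell cycle genes at 12 of 22 (0.442), ribosomal protein genes at 6 of 30 (1.0), blood genes at 2 of 14 (0.442) and liver genes at 6 of 16 (1.0). The forkhead family had peaks at 17 of 23 (0.276), with Foxp1 at 42, Foxp2 at 14, Foxf1 at 11 and Foxl1 at 9. It passed under 3 planned settings: the higher-scored part of the peaks (adjusted p = 0.0101, n = 23), peaks within 10 kb of a TSS (0.0126) and Fisher's exact test without matching (0.00186). It also passed when the mean number of peaks per gene was compared, 6.30 against 2.67 in random lists (adjusted p = 0.00168, n = 23, a measure added after the data were seen). Foxp1 alone held 42 of the 145 peaks behind that mean.

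**Figure D5:**
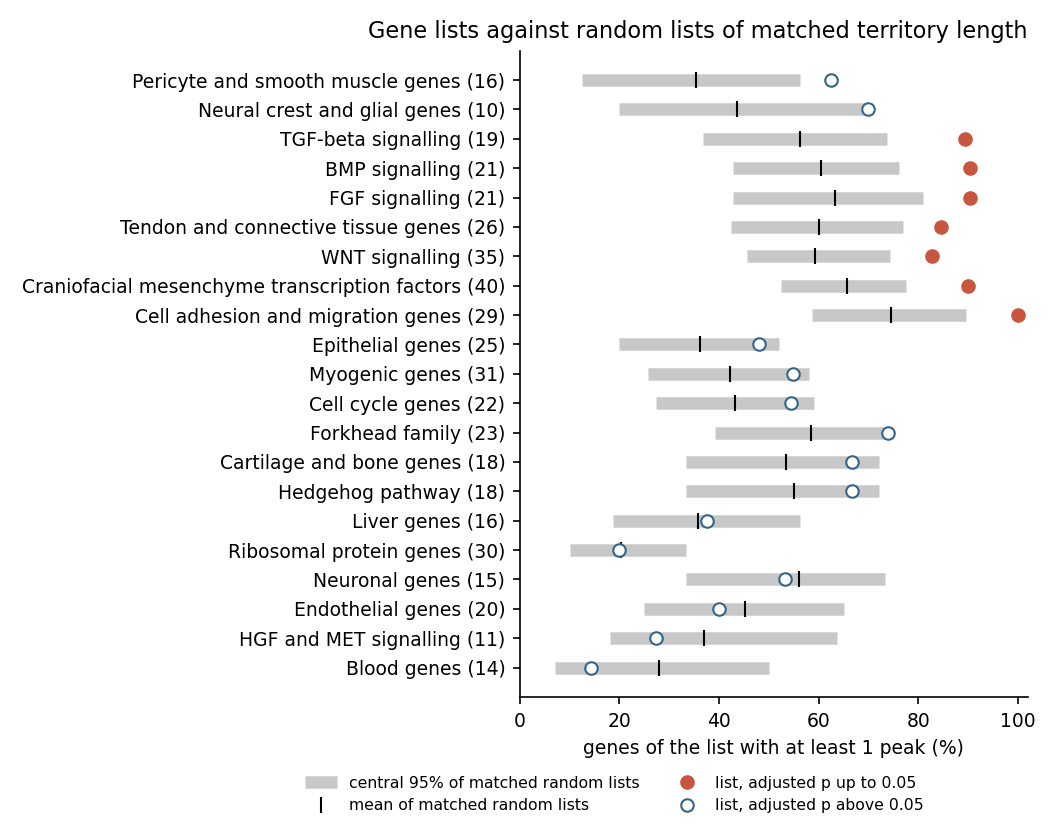
Share of genes with at least 1 peak (x axis, percent) in each of 21 gene lists (number of genes in brackets). Grey bars are the central 95% of 10000 random lists matched on territory length, ticks their mean; the 7 filled points, adjusted p of up to 0.05, all lie above their bars.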

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

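The focus ratio of the peaks was used in no comparison of the report. The RE1 search, the tests against base composition and the alternative mismatch limits were chosen only after the sequences of sharp peaks had been seen. Among the 354 peaks of the sharpest decile (focus ratio from 0.871) that lacked a forkhead match, 36, or 10.2% (exact 95% interval 7.22 to 13.8), held a match to RE1, the 21-base element bound by REST, a repressor of neuronal genes. It is set apart because it lies in a column not used before and above the 0.847% that a count of 0 would have allowed; as the motif was picked from these same peaks, this is a description and no test. In the 1386 such peaks of the least sharp decile there were 0. Sharpness was not particular to RE1. Matches to a 19-base CTCF sequence, with up to 4 mismatches, were in 8 (2.26%) of the 354 and 3 (0.216%) of the 1386. Of all peaks with a CTCF match and no RE1 match, 32.3% lay in the sharpest decile, against 9.72% of peaks with neither. Over the whole list 105 peaks held an RE1 match with up to 4 mismatches, and their mean focus ratio was 0.858 against 0.777 for the other peaks, a difference for which a permutation test was run and set aside as circular, since sharp peaks prompted the search. Examples with 1 mismatch lie in an intron of Npas4, 1.138 kb downstream of its TSS (score 84.7, chromosome 19, 4989072 to 4989284, sequence TTCAGCACCGCGGACAGCTCC), and 22.4 kb upstream of the potassium channel gene Kcnk9 (score 77.6, chromosome 15, 72568621 to 72568833, sequence CTCAGCACCGTGGACAGCGCC). Both were chosen after their values were seen.

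Chance matches at this base composition predict a ratio of 1 to random windows, which were matched on GC content only. They were argued against as the sole cause only under a bound of 1 chosen after the result was seen. Sharp peaks with a forkhead match had not prompted the search, though their sequences were counted with all others. Among them 19 of 2217 against 3 windows gave a ratio of 6.33 (95% interval 1.86 to 33.4). This interval fell short of a stricter bound of 2 that was set first, and under that bound chance matches stay open. The ratio was 2.94 (1.67 to 5.44) outside the sharpest decile and 3.45 (2.07 to 5.99) without the 354 peaks that prompted the search. Over all peaks it was 5 (3.11 to 8.41). Tandem repeats stay open, since 36 of the 105 windows held more than 1 match and the ratio for exactly 1 match, which includes the peaks that prompted the search, was 3.29 (1.99 to 5.64) against a bound of 2. Recovery of open chromatin in general stays open too: of the places with an RE1 match in the genome, 1.77% lay in peaks (interval 1.45 to 2.13), against 2.14% (1.79 to 2.53) for full-length CTCF matches, while with up to 3 mismatches the shares were 6.10% (4.84 to 7.57) and 4.08% (2.97 to 5.46), and no biological explanation was tested.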

How the results depend on the processing

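The report's results were recomputed with other peak sets, windows, motif forms, backgrounds and distances. Exclusion of RE1 or CTCF peaks, RefSeq TSS, 50 bins, the mean number of peaks, the list without Tcf4 and the strata of GC and score were chosen after seeing the data. The 1 result whose direction turned was the odds ratio of a forkhead match in promoter peaks, which was 1.03 (p = 0.548 by Fisher's exact test) with the strict sequence GTAAACA. It was 0.483 to 0.757 under the other 4 alternatives and 0.538 in the report, and the cause was not tested. Within deciles of GC content GTAAACA gave 0.951 (95% interval 0.856 to 1.06), on both sides of 1. The enrichment of forkhead matches over background held in all 8 alternatives, from 2.31-fold with 400 bp windows to 9.04-fold with GTAAACA, and rho against the score stayed between 0.0906 and 0.199 over its 6 alternatives. The promoter share ran from 7.67% for the higher-scored peaks to 18.2% for the wider promoter, above random placement each time. The number of gene lists called ran from 6 to 10, the latter without matching on territory, and the calls that changed were those of the WNT, FGF, Hedgehog, forkhead, and cartilage and bone lists. No paired analysis was possible because the table holds no values per library, and for the same reason leaving out a replicate and the fold threshold over input were not run. The unknown depth limits what a missing peak says: a gene without a peak was not shown to be unbound.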

Other observations

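Promoter peaks carried other sequences than the rest. The GC-rich SP and KLF sequence was in 5.20% of promoter peaks and 0.549% of the others, the ETS sequence in 3.01% and 0.2%, and the TFAP2 sequence in 12% and 4.64%. CATCTG ran the other way, with 14.1% in promoter peaks and 29.2% elsewhere, as did the TEAD sequence with 11% and 18.4%. These differences were not tested.

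Of 6 forms that join a forkhead core to an E-box, 2 were more frequent in peaks than in flanks. The sequence RTAAAYACAGCTG, a forkhead core followed at once by CAGCTG, occurred 96 times in 95 peaks, and 0 times after 11831 forkhead matches in the flanks, which allows a share of up to 0.0254% against 0.376% in peaks. The cores behind these shares were not alike. The form RTAAACA was counted 18970 times in peaks and 4547 times in flanks, a larger part of all cores in peaks. RTAAAYACATCTG occurred 37 times in peaks and 4 times in flanks (adjusted Fisher's exact p = 0.00604), and the other 4 forms, among them RTAAACAGCTG (0.164), were not separated. Peaks with RTAAAYACAGCTG were nearest to 93 genes, 6 of them in the gene lists: Bmp2, Fgfr2, Tnc, Nrp2, Slit3 and Fzd6. Those of Slit3 and Fzd6 lay 5.89 and 12.7 kb from the TSS. The others were remote: 68.2 and 354 kb for Bmp2, 178 kb for Nrp2, 273 kb for Fgfr2 and 537 kb for Tnc. Whether list genes were more frequent here than among all peaks was not tested. The highest-scored peaks with this sequence were nearest to Eya2 (rank 5 in the whole list), Bbx, Lmo4 and Ccdc33. These genes were named after their values were seen.

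The tests of chance adjacency, of the frequency of both motifs and of a single active X copy were chosen only after the result was seen, and the form with CAGCTG is 1 of 6 joined forms that were counted then. For the forkhead core followed by CAGCTG, the frequency of both motifs in peaks was argued against as the sole cause: CAGCTG was 3.84 times as frequent directly after the core as at the median of the other 60 distances (95% interval 3.11 to 4.69), with 44 as the highest of those counts. Copies of a repeat were argued against as well, with 9.47% of these peaks having the match in repeat-masked sequence (exact 95% interval 4.42 to 17.2). For the overlapping form RTAAACATCTG chance adjacency cannot be told apart, as its share of cores was 0.691% in peaks and 0.484% in flanks, a ratio of 1.43 (95% interval 0.910 to 2.24). A joint site of a forkhead and a helix-loop-helix factor is a hypothesis for the form with CAGCTG, and no design group bears on it.

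Peaks were sparse on the X chromosome, at 2.24 per Mb (95% interval 2.02 to 2.49) against 10.6 on the autosomes, and 20.4% of X genes had a peak against 38.3% of autosomal genes. Fewer forkhead sequences were argued against, since X held 1.12 times the autosomal number per Mb, and 0.957 times outside repeats. Less sequence outside repeats was argued against too, as peaks per Mb outside repeats were still 0.265 times the autosomal value (interval 0.239 to 0.294). A single active copy would lower the signal to 1 part in 2, and autosomal peaks counted from 2 times the lowest score were 3.71 per Mb, above the X interval; autosomes came down to the X density from a score of 26.9, which is 2.66 times the lowest. This last test takes the score as proportional to reads, which the sources do not state, so a contribution of copy number may remain, and no biological explanation was tested.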
